A study of Pyrus pyrifolia with 6 samples.

How the data were processed

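Fruit skin of the pear Pyrus pyrifolia, cultivar Cuiguan, was measured by RNA sequencing in 6 libraries, 3 from fruits left without bags and 3 from fruits grown in paper bags. Per the labels' protocols, single-layer white bags went on at 20 days after full bloom and double-layer bags at 40 days, and all fruits were sampled at 95 days. RNA was extracted with CTAB and libraries were made with an NEBNext Ultra RNA kit, and the labels speak of biological replicates without saying how many fruits or trees each one holds.

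The deposited table gives, per gene and library, the raw read count and the FPKM made by the authors. HISAT2 is the aligner per the submitters' processing notes. The counter, its strand setting, the genome build and the annotation are not given in the sources used here, so scaffold names and positions are printed as the authors listed them, and reads of overlapping or antisense genes cannot be told apart. The authors' FPKM equals the count divided by the listed gene length and the column sum, times 1 factor per library between 0.967 and 1.02. The table also holds the authors' group means as a scaled signal (not used here), their log2 fold change, and their p-value and adjusted p-value, all per the file headers, with the test not named. Gene descriptions come from the same table. For 5922 of the tested genes there is none or one that begins with uncharacterized, and both kinds count here as lacking a description.

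Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. The table lists 42933 genes, of which 9356 have no count in any library. The filter of filterByExpr (minimum count 10, minimum total 15) left 25139 genes, scaled by TMM factors. The quasi-likelihood test compared bagged with untreated fruits with no covariate, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are log2 of bagged over untreated, and their standard errors (SE) are the fold change divided by the square root of the F statistic. Library totals were 17136285, 19278100 and 15764049 counts for untreated replicates 1 to 3 and 16735371, 17905890 and 19546285 for bagged replicates 1 to 3. The median SE of a log2 fold change was 0.17 and the common biological coefficient of variation 20.1%. No 2 libraries of the same group agreed within counting noise (chi-square per degree of freedom 12.1 to 20.5), so none was taken for a repeated measurement of another. That each library is a biological replicate rests on the labels.

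Before the data were examined, 28 gene lists were fixed as text patterns on the gene descriptions: suberin, cutin, cuticular wax, lipid transfer proteins, monolignol synthesis, laccases and class III peroxidases, flavonoid and anthocyanin synthesis, triterpene synthesis, photosynthesis, light signalling, circadian clock, heat shock proteins, abscisic acid, ethylene, auxin, gibberellin, jasmonate, cell wall loosening and pectin, MYB, NAC and WRKY transcription factors, defence proteins, antioxidant enzymes, cell division, and, for other tissue in a peel, flesh sugar metabolism, phloem and xylem and the secondary wall of stone cells, with cytosolic ribosomal proteins as a check. A list needed 5 tested members. The patterns also took in 2 regulators of peroxidase expression, 4 regulators of pigment synthesis and some regulators of defence genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over the 28 lists, and again with the correlation estimated per list. Named genes were the 5 highest and 5 lowest fold changes among called genes that had a description, an average log2 CPM of at least 2 and no overlap between groups, and up to 2 such members per list (1 for the check list), which gave 48 genes. Genes outside this rule are said to be so where named.

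The gene-wise test was tested on simulated data, 10 sets with 200 changed genes each among the 25139 genes. With variances that follow the fitted trend, 58.0% of 2-fold and 92.5% of 4-fold changes were called, and 4.66% of the calls were false. With the gene-wise variances estimated from these libraries, 44.9% of 2-fold and 82.9% of 4-fold changes were called and 10.6% of the calls were false, about double the nominal rate. Of those false calls 89.0% fell in the 1828 genes whose dispersion exceeds the trend more than 2-fold. A limit of 10 percent on false calls had been set for this check, and the gene-wise simulation exceeded it. The test was kept as planned, the limit was then applied to the trend simulation alone, and the robust version of the test, tried afterwards, gave 11.6% false calls in the gene-wise simulation. In the measured data 111 of the called genes, 16.6%, have such a dispersion.

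Alternatives were other scalings (RLE factors, upper quartile, library size alone), no filter or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 libraries, a replicate block, stricter thresholds and each library left out in turn. The robust fit and the list counts without each library were added after seeing the data. A scan of 308 gene families, groups of at least 10 tested genes that share a description up to its number, was also added after seeing the data, with 1-sided Fisher's exact tests against the 18472 genes with a family. It was repeated without each library and with the calls of DESeq2, and the families were also tested with camera. Recently duplicated pear genes can share reads, and how the authors treated such reads is not given in the sources used here.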

Results

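The transcriptome of fruit skin was compared between untreated and bagged fruits of Cuiguan, a sand pear whose skin russets in part, that is, forms patches of corky tissue in place of a smooth cuticle. Bagging shields the growing fruit from light, wetting and abrasion, and the series was made to study how russet forms in this variety. There were 3 libraries per group, all from fruits sampled at 95 days after full bloom, and bagged fruits had been covered from 20 days on. Library totals ran from 15764049 to 19546285 counts, and between 29949 and 30749 genes had a count in each library.

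The groups separated on the first principal component of log2 CPM, which held 46.8% of the variance. Bagged libraries lay between 40.1 and 50.3 on it, untreated replicates 1 and 2 at -52.0 and -59.8, and untreated replicate 3 nearer to the bagged libraries, at -24.0. Spearman correlations were 0.978 to 0.982 within groups and 0.956 to 0.974 between groups. The second component, with 15.5% of the variance, spread the replicates of each group.

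**Figure D1:**
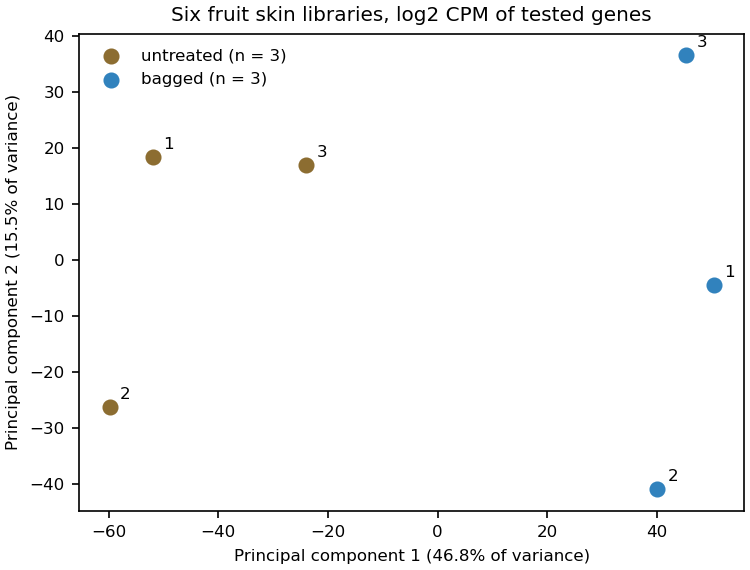
Principal components 1 and 2 of log2 CPM over the 25139 tested genes, with 1 point per library, coloured by group and numbered by replicate. The 3 bagged libraries lie at 40.1 to 50.3 on component 1, and untreated replicate 3, at -24.0, lies closer to them than the other untreated libraries.

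The skin of bagged fruits held far fewer transcripts of the suberin pathway, the cork polymer of russeted skin, than that of untreated fruits. Of 18 suberin genes tested, 13 fell and none rose, with a median log2 fold change of -2.79 over the list. Of the lipid transfer proteins 9 of 24 genes fell, of monolignol synthesis 14 of 71, of laccases and peroxidases 11 of 34 and of MYB regulators 15 of 65, with 1 to 3 genes higher in each of these lists. Of the cutin genes 3 rose and 1 fell, of the triterpene genes 4 rose and 2 fell, and of 63 WRKY regulators 7 rose and 5 fell. Most of these list counts depend on single libraries, as given with each list below. Genes of photosynthesis, the clock, heat shock and cell division held 0 to 3 changed genes each. In all, 670 of 25139 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 244 higher and 426 lower in bagged skin. The median log2 fold change was 1.17 for the genes that rose and -2.57 for those that fell, and 527 genes changed at least 2-fold, 152 higher and 375 lower. The count fell to 306 or 292 without untreated replicate 1 or 2 and to 205, 248 or 420 without bagged replicate 1, 2 or 3, with 70 to 306 genes higher and 135 to 386 lower over all 6 libraries left out in turn, and DESeq2 called 1501 genes, 756 higher and 745 lower. In simulations of this comparison with the gene-wise variances of these libraries, 10.6% of the calls were false, most of them in genes with a dispersion far above the trend. Each simulated set held 200 changed genes, so this share is not an estimate for the 670 calls. Protein-coding genes made up 232 of the higher and 401 of the lower genes (22749 tested), and long noncoding RNAs 1 and 7 (913 tested). Pseudogenes made up 5 and 8 (914 tested), and assembled loci without annotation 5 and 9 (476 tested).

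Among the named genes, the largest fall was that of LOC103944820, described as an ABC transporter G family member 36-like gene, on scaffold NW_008988067.1 from 242786 to 252825. It went from 14.5 ± 5.46 CPM (SD, n = 3) in untreated to 0.203 ± 0.124 CPM in bagged skin, a log2 fold change of -6.08 ± 0.47 (SE), with an edgeR adjusted p of 0.0058. A pair of abscisic stress-ripening genes, which code for small hydrophilic proteins of water stress and ripening, stood close together on scaffold NW_008988326.1 and both fell. LOC103965244 (144967 to 146223) fell by 5.61 ± 0.44 on the log2 scale and LOC103965247 (108827 to 123596) fell by 4.87 ± 0.39, the latter from 61.1 ± 29.1 to 2.09 ± 0.469 CPM. The span of LOC103965247 overlaps LOC103965245 on the other strand, which has 355 counts in all. The remaining largest falls were those of the mandelonitrile lyase 2-like gene LOC108867073, of a family that splits cyanogenic compounds (-4.18 ± 0.48), and of the auxin-induced ARG7-like gene LOC103929026 (-4.13 ± 0.33).

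Among the genes within the naming rule, which asks for an average log2 CPM of at least 2, the highest fold change was that of LOC103952209, a mitochondrial ubiquinol oxidase-like gene (alternative oxidase, which bypasses part of the respiratory chain), on scaffold NW_008988128.1 from 420692 to 422569. It rose from 0.93 ± 0.378 to 15.9 ± 6.63 CPM (SD, n = 3), a log2 fold change of 4.11 ± 0.45 with an edgeR adjusted p of 0.0079. The patatin-like protein 2 gene LOC103956492, of a family of lipid acyl hydrolases, rose by 3.68 ± 0.70 and the salicylate carboxymethyltransferase-like gene LOC103967120 by 3.60 ± 0.67. The WRKY70 gene LOC103953732 rose from 5.18 ± 3.38 to 58.1 ± 23.8 CPM (3.50 ± 0.49), and LOC103966167, a heavy metal-associated isoprenylated protein 3-like gene, by 3.03 ± 0.54. Adjusted p-values of these 4 genes lay between 0.015 and 0.041 (edgeR), and none of these calls held throughout with 1 library left out. The call of LOC103956492 was lost without any library but bagged replicate 2 (adjusted p 0.0532 to 0.132). The call of LOC103967120 was lost without untreated replicate 1 or 2 or bagged replicate 1 or 3 (0.0734 to 0.127). That of LOC103953732 was lost without untreated replicate 1 (0.063) or bagged replicate 1 (0.0607). That of LOC103966167 was lost without any library but untreated replicate 3 (0.0668 to 0.118). LOC103956492 and LOC103967120 also missed the threshold with limma-voom (0.128 and 0.12).

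Suberin is a polyester of fatty acids and glycerol bound to aromatic units, and genes for each of these steps fell. The fatty acid hydroxylase gene for cytochrome P450 86A1, LOC103963213 (scaffold NW_008988284.1, 195855 to 197654), went from 28.8 ± 6.83 to 3.03 ± 1.24 CPM (SD, n = 3), a log2 fold change of -3.24 ± 0.31. The transporter gene LOC103932967, ABC transporter G family member 20-like, went from 34.3 ± 10.96 to 3.57 ± 1.81 CPM (-3.25 ± 0.37). Outside the naming rule, and chosen after their values were seen, the glycerol-3-phosphate acyltransferase 5-like genes LOC103942961 and LOC103935642 fell by 2.81 and 2.80, and 4 omega-hydroxypalmitate O-feruloyl transferase-like genes were among the 13. Adjusted over the list alone, 16 suberin genes fell and none rose, and camera placed the list below other genes (adjusted p = 5.54e-17, and adjusted p = 0.331 with an estimated correlation). The number that fell was 8 without bagged replicate 2 and 10 to 13 without any other library.

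Of 16 tested genes of cutin, the polyester of the smooth cuticle, 3 rose, 1 fell and 12 did not pass (9 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.59. The cytochrome P450 86A22 gene LOC103963865 rose from 49.3 ± 16.2 to 152 ± 55.5 CPM (1.62 ± 0.32), and the transporter gene LOC103962994, ABC transporter G family member 32-like, fell from 107 ± 29.9 to 13.3 ± 6.09 CPM (-2.998 ± 0.33; SD, n = 3). Camera placed the list above other genes (adjusted p = 0.0071, and adjusted p = 0.462 with an estimated correlation), a call lost without bagged replicate 3 (adjusted p = 0.0976). No cutin gene rose without untreated replicate 1 or without any 1 of the bagged replicates, and 1 rose without untreated replicate 2. Without bagged replicate 2, 2 cutin genes fell. The call of LOC103963865 was lost without each of the 6 libraries (adjusted p 0.0547 to 0.119).

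**Figure D2:**
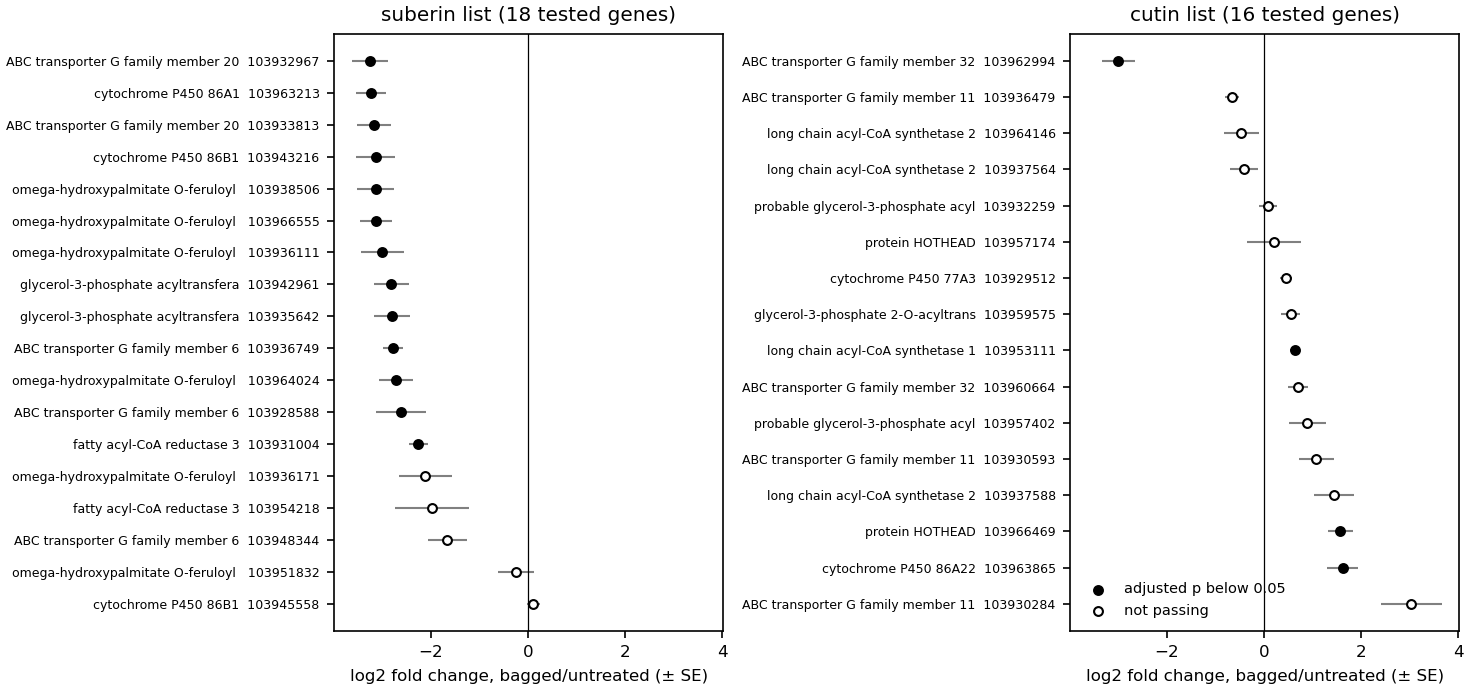
Log2 fold change of bagged over untreated skin for the 18 tested suberin genes and the 16 tested cutin genes, with the standard error as bars and the digits of the gene symbol beside the description. Filled points pass an adjusted p of 0.05. In the suberin list 13 genes are filled, all below 0, and in the cutin list 3 filled genes lie above 0 and 1 below.

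Genes of cuticular wax went both ways, with 5 of 44 higher and 3 lower (11 and 6 adjusted over the list alone), a median of 0.20 and a mean of -0.03. The 3-ketoacyl-CoA synthase 6 gene LOC103947136, of the enzymes that lengthen fatty acids for wax, rose by 1.53 ± 0.25, and the 3-ketoacyl-CoA synthase 4-like gene LOC103966995 fell by 2.79 ± 0.52. LOC103947136 overlaps a gene of similar description, LOC103947140, on the same strand, so reads of this pair were not separated with certainty. The wax list missed the camera threshold, in the upward direction (adjusted p = 0.0755), and passed it under 2 other scalings, both other filters and without bagged replicate 1. The wax genes that rose numbered 1 without untreated replicate 2 or bagged replicate 2 or 3, 2 without untreated replicate 1 and 3 without untreated replicate 3 or bagged replicate 1. Those that fell numbered 0 without bagged replicate 1 or 2 and 1 without untreated replicate 1 or 2. The wax median was 0.11 without bagged replicate 3. The call of LOC103947136 was lost without any library but untreated replicate 3 (adjusted p 0.0522 to 0.0788). That of LOC103966995 was lost without untreated replicate 1 or 2 or bagged replicate 1 or 2 (0.099 to 0.136), with limma-voom (0.0634) and with the replicate number as a block (0.0785). Lipid transfer proteins, which carry lipids to the wall, had 9 of 24 genes lower and 2 higher (13 and 4 adjusted over the list alone), with a median of -0.53. The neighbouring genes LOC103957214 and LOC103957215 fell by 3.42 ± 0.34 and 3.02 ± 0.37, and camera gave an adjusted p of 0.0001 (adjusted p = 0.331 with an estimated correlation). The lipid transfer genes that fell numbered 5 without bagged replicate 1, and those that rose 0 without untreated replicate 1 or bagged replicate 2 and 1 without any other library. Their median was -0.30 without untreated replicate 1 and -1.02 with no low-count filter. The call of LOC103957215 was lost without bagged replicate 1 (adjusted p = 0.0534).

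Monolignol synthesis, which makes the precursors of lignin, had 14 of 71 genes lower and 3 higher (28 and 10 adjusted over the list alone), with a median of -0.26. The caffeoyl-CoA O-methyltransferase-like gene LOC103933993 fell from 40.1 ± 11.9 to 4.94 ± 0.974 CPM (-3.02 ± 0.25; SD, n = 3), and the cinnamyl alcohol dehydrogenase 1 gene LOC103951786 fell by 1.91 ± 0.21. Laccases and class III peroxidases, which join monolignols in the wall, had 11 of 34 genes lower and 1 higher (12 and 3 adjusted over the list alone), with a median of -0.21. The laccase-7-like gene LOC103938691 went from 185 ± 87.2 to 17.5 ± 5.81 CPM (-3.40 ± 0.37) and the peroxidase 11 gene LOC103946699 fell by 3.47 ± 0.37. Camera placed both lists below other genes (adjusted p = 0.00025 and 0.0039), which did not hold with an estimated correlation (adjusted p = 0.307 and 0.331). Without untreated replicate 1 the laccase and peroxidase list missed the threshold (adjusted p = 0.0607). The monolignol count of lower genes was 8 to 9 without bagged replicate 1, bagged replicate 2 or untreated replicate 2, and that of laccases and peroxidases was 7 without bagged replicate 1. No laccase or peroxidase gene rose without any library other than bagged replicate 3. The monolignol median was -0.44 without bagged replicate 2 and -0.40 with no low-count filter, and the laccase and peroxidase median was -0.10 without untreated replicate 1 and -0.75 with no low-count filter.

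Flavonoid and anthocyanin synthesis had 5 of 39 genes lower and none higher (6 and 2 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.0755 (0.0193 without untreated replicate 2). The leucoanthocyanidin reductase-like gene LOC103929197, of proanthocyanidin synthesis, fell by 2.56 ± 0.23, and the flavanone hydroxylase gene LOC103953484 fell by 0.98 ± 0.13. The flavonoid genes that fell numbered 3 without untreated replicate 1 or bagged replicate 1 and 2 without any other library. Without untreated replicate 1 their median was -0.09 and 1 rose, and with no low-count filter the median was -0.13. Triterpenes, which fill the waxy cuticle of pear, had 4 of 28 synthesis genes higher and 2 lower (14 and 4 adjusted over the list alone), with a median of 0.55. Both named members, the beta-amyrin synthase-like genes LOC103935920 and LOC103939378, were among the 2 that fell (-2.27 ± 0.36 and -1.80 ± 0.35). Outside the naming rule, and chosen after their values were seen, the 4 that rose were the beta-amyrin synthase genes LOC103967646 (0.81 ± 0.08) and LOC103927760 (0.87 ± 0.17) and the beta-amyrin 28-oxidase-like genes LOC103965050 (1.27 ± 0.24) and LOC103945098 (1.15 ± 0.18). Camera placed the triterpene list above other genes (adjusted p = 0.00016, and adjusted p = 0.389 with an estimated correlation). The number that rose was 1 without any 1 of the bagged replicates and 2 without untreated replicate 2, and the number that fell was 0 without bagged replicate 1 or 2 and 1 without untreated replicate 1 or 2. The call of LOC103935920 was lost without bagged replicate 1 or 2 (adjusted p = 0.0839 and 0.0869). That of LOC103939378 was lost without these and untreated replicate 1 or 2 (0.0719 to 0.143).

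**Figure D3:**
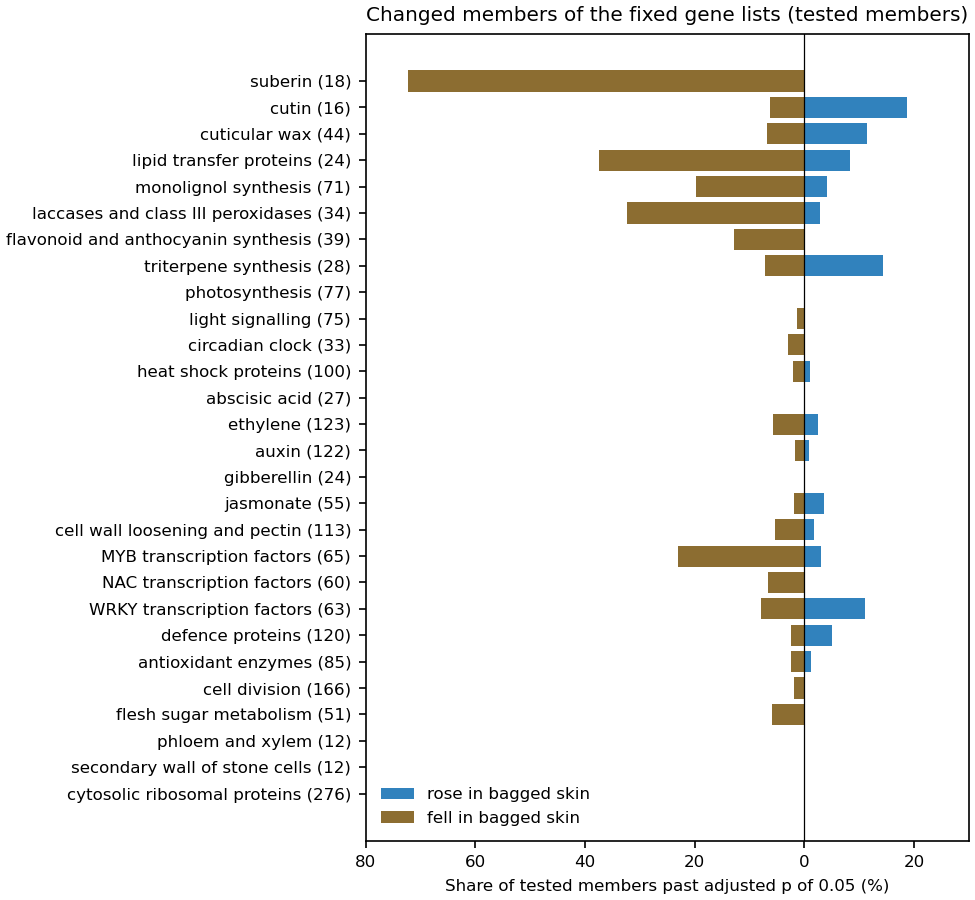
Share of the tested members of each of the 28 gene lists that rose (right of 0) or fell (left of 0) in bagged skin, in percent, with the number of tested members in brackets. Suberin, with 13 of 18 members lower, has the longest bar.

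MYB transcription factors had 15 of 65 genes lower and 2 higher (24 and 12 adjusted over the list alone), with a median of -0.30 and a camera adjusted p of 0.00097 (adjusted p = 0.307 with an estimated correlation). The MYB39-like genes LOC103960041 and LOC103939715, of a subgroup known to control suberin genes, fell by 3.70 ± 0.47 and 3.64 ± 0.32. The MYB genes that fell numbered 9 without untreated replicate 1 or 2, 4 without bagged replicate 1 and 3 without bagged replicate 2. Those that rose numbered 6 without untreated replicate 3, 5 with the replicate number as a block, and 1 without untreated replicate 1 or 2 or bagged replicate 1 or 2. NAC transcription factors had 4 of 60 genes lower and none higher (6 lower and none higher adjusted over the list alone), with a camera adjusted p of 0.0755 (0.0482 without untreated replicate 2, 0.011 without bagged replicate 1 and 0.0429 under the CPM filter), and the NAC100-like genes LOC103957499 and LOC103937057 fell by 2.42 ± 0.33 and 2.38 ± 0.37. The NAC genes that fell numbered 0 without bagged replicate 2, 1 without bagged replicate 1 and 2 without untreated replicate 1 or 2 or bagged replicate 3, and 2 rose without untreated replicate 3 or with the block. WRKY transcription factors, which regulate defence and stress genes, went both ways, with 7 of 63 higher and 5 lower (13 and 12 adjusted over the list alone), a median of 0.01 (-0.01 without untreated replicate 2 or bagged replicate 1), a mean of 0.42 and a camera adjusted p of 0.57. The second WRKY70 gene, LOC103952818, rose from 4.34 ± 2.97 to 33.3 ± 14.9 CPM (SD, n = 3), a log2 fold change of 2.95 ± 0.52. On the other strand 2 genes overlap it, with 2259 and 1496 counts in all. The WRKY genes that rose numbered 1 without untreated replicate 1 or bagged replicate 1, 2 without untreated replicate 2 and 3 without bagged replicate 3. Those that fell numbered 0 without bagged replicate 1, 1 without untreated replicate 1 or 2 or bagged replicate 2, and 2 without bagged replicate 3 or with the block. The call of LOC103960041 was lost without bagged replicate 2 (adjusted p = 0.0516). Those of LOC103957499 and LOC103937057 were lost without bagged replicate 1 (0.0689 and 0.077) or 2 (0.0568 and 0.08). That of LOC103952818 was lost without untreated replicate 1 or 2 or bagged replicate 1 or 3 (0.0734 to 0.101).

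**Figure D4:**
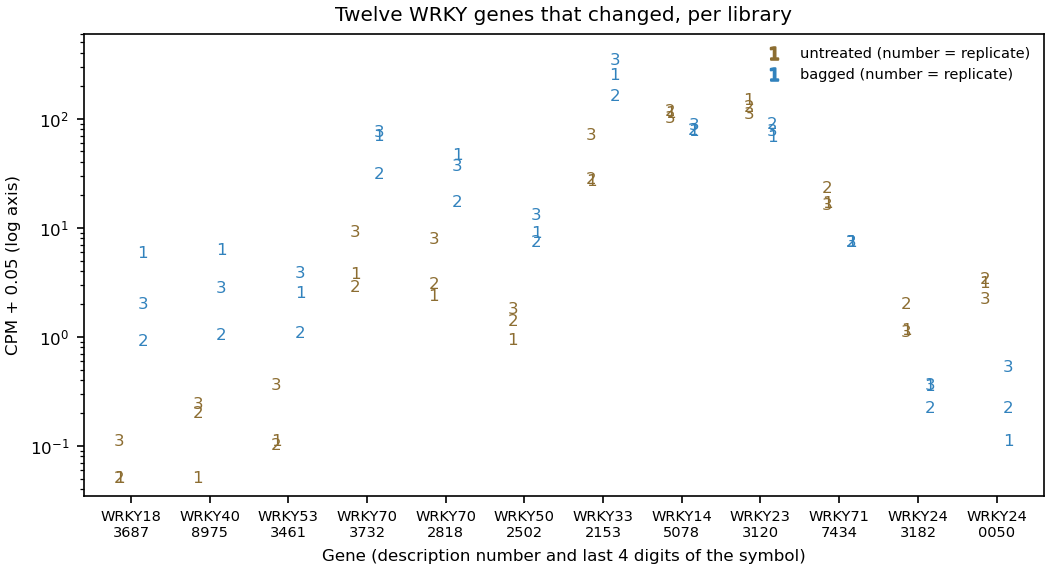
CPM (plus 0.05, on a log axis) of the 12 WRKY genes that changed, in each library, with the replicate number as the symbol and the group as the colour. For the 7 genes that rose, untreated replicate 3 was the highest of the untreated libraries.

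Among hormone lists, ethylene genes had 3 of 123 higher and 7 lower (10 and 11 adjusted over the list alone), with a median of 0.11 (0.05 with no scaling factors). The ethylene-responsive factor 5-like gene LOC103926617 rose by 1.84 ± 0.27 and the RAP2-3 gene LOC103959375 fell by 1.72 ± 0.30. The ethylene counts were 10 higher and 4 lower without untreated replicate 3, none without bagged replicate 1, and 0 or 1 higher and 3 or 4 lower without any other library, with 8 higher under the block and 6 with limma-voom or with no low-count filter. Camera placed the list above other genes (adjusted p = 0.0454, and adjusted p = 0.345 with an estimated correlation), a call lost without untreated replicate 1 (0.108) or 2 (0.0575), without bagged replicate 1 (0.0774), 2 (0.077) or 3 (0.0501), and under the CPM filter (0.0797). Jasmonate genes had 2 of 55 higher and 1 lower (9 and 2 adjusted over the list alone), with a median of 0.12. The 12-oxophytodienoate reductase 3-like gene LOC103929738, of jasmonate synthesis, rose by 0.83 ± 0.17, and the 13-lipoxygenase gene LOC103954907 fell by 0.99 ± 0.13. Camera gave the jasmonate list an adjusted p of 0.0071 (adjusted p = 0.345 with an estimated correlation), lost without bagged replicate 1 (0.0782). The jasmonate genes that rose numbered 6 without untreated replicate 3, 4 with no low-count filter, 1 without untreated replicate 1 or bagged replicate 2, and 0 with no scaling factors or without untreated replicate 2 or bagged replicate 1 or 3. None fell without bagged replicate 2. The jasmonate median was 0.22 without untreated replicate 1, 0.24 without bagged replicate 3, 0.18 under the CPM filter and 0.06 with no scaling factors. Auxin genes had 1 of 122 higher and 2 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.543), among them the SAUR36-like gene LOC103964554 (1.59 ± 0.23). The auxin genes that rose numbered 0 without untreated replicate 1 and 2 without untreated replicate 2. Those that fell numbered 4 without untreated replicate 3, 1 without untreated replicate 1 or bagged replicate 1 or 2, 5 with upper quartile or no scaling factors and 7 with no low-count filter. No tested abscisic acid gene (27) or gibberellin gene (24) passed, over all genes or adjusted over the list alone, with DESeq2 calling 1 lower and 1 higher gene respectively, and camera adjusted p-values were 0.885 and 0.237. Without untreated replicate 3, 1 gene of each of these 2 lists rose, as did 1 abscisic acid gene with the block, and 1 abscisic acid gene fell without bagged replicate 3. The abscisic acid list had a median of 0.04 (-0.01 without untreated replicate 2 or 3, -0.06 without bagged replicate 2, -0.02 with no scaling factors), a mean of -0.05 and a downward camera direction. With 1 library left out, the call of LOC103926617 was lost without untreated replicate 1 or 2 or bagged replicate 1 or 2 (adjusted p 0.0522 to 0.0689). The call of LOC103959375 was lost without untreated replicate 1 or 3 or bagged replicate 1 or 3 (0.0505 to 0.127). That of LOC103954907 was lost without bagged replicate 2 (0.0502) and that of LOC103964554 without untreated replicate 1 or 2 or bagged replicate 1 (0.0511 to 0.0611). The call of LOC103929738 was lost without any library but untreated replicate 3 (0.081 to 0.152), with no scaling factors (0.0603) and with the block (0.0865).

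Photosynthesis genes were lower in 71 of 77 cases, with a median log2 fold change of -0.47, though none passed the gene-wise test over all genes or adjusted over the list alone, and DESeq2 called 3 lower. The list passed camera (adjusted p = 3.54e-06, and adjusted p = 0.648 with an estimated correlation), and untreated replicate 1 stood apart, at 0.84 above the mean of the libraries against -0.10 and -0.08 in the other untreated libraries (log2). Without it the median was -0.10 and the adjusted p 0.068. Light signalling had 1 of 75 genes lower (1 adjusted over the list alone, camera adjusted p = 0.367) and the circadian clock 1 of 33 (3 adjusted over the list alone, camera adjusted p = 0.17). Heat shock proteins had 1 of 100 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.253), with the B-1-like heat stress factor LOC103942246 lower by 1.05 ± 0.13 and the peroxisomal 15.7 kDa gene LOC103959434 higher by 0.53 ± 0.09. No light signalling gene fell without untreated replicate 1 or 2 or bagged replicate 2, and no clock gene without untreated replicate 1 or 2 or bagged replicate 1 or 2, while 2 clock genes fell with upper quartile or no scaling factors, under the CPM filter or with the block. The heat shock genes that rose numbered 3 without bagged replicate 3, 4 with the block and 0 without untreated replicate 1 or 2 or bagged replicate 1 or 2. Those that fell numbered 0 without bagged replicate 1 and 1 without any other library. The call of LOC103942246 was lost without bagged replicate 1 (adjusted p = 0.0519), and that of LOC103959434 without each of the 6 libraries (0.0512 to 0.0865).

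Defence proteins had 6 of 120 genes higher and 3 lower (17 and 9 adjusted over the list alone, camera adjusted p = 0.0804). The defence list passed camera upward without untreated replicate 2 (0.0482), under upper quartile factors (0.0452) and with no factors (0.0224). The endochitinase-like gene LOC103929599 rose by 2.08 ± 0.22 and the glucan endo-1,3-beta-glucosidase 7-like gene LOC103939937 fell by 2.20 ± 0.23, and the defence genes that rose numbered 1, 2 and 3 without bagged replicates 1, 2 and 3, and those that fell 5 without bagged replicate 2 or with the block. Antioxidant enzymes had 1 of 85 higher and 2 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.363), and the 2 named glutathione S-transferase genes went opposite ways, LOC103967342 (-3.81 ± 0.39) and LOC103935192 (1.01 ± 0.10). LOC103967342 overlaps LOC103967343, with 720 counts, on the same strand. Without untreated replicate 1 or 2 or bagged replicate 1 or 3, 1 antioxidant gene fell. Cell wall loosening and pectin genes had 2 of 113 higher and 6 lower (6 and 10 adjusted over the list alone, camera adjusted p = 0.504), with a median of 0.04 (-0.02 with no scaling factors and -0.05 with no low-count filter), a mean of -0.12 and an upward camera direction. The pectinesterase 29 gene LOC103963535 fell by 3.19 ± 0.45 and the xyloglucan endotransglucosylase 31-like gene LOC103947710 by 2.65 ± 0.45. The cell wall genes that fell numbered 1 without bagged replicate 1, 2 without bagged replicate 2 and 4 without untreated replicate 1 or 2, and those that rose 1 without untreated replicate 1 or 3 or bagged replicate 2. The cell wall median was 0.11 without untreated replicate 1, 0.01 without untreated replicate 2 and 0.07 without bagged replicate 2. Cell division had 3 of 166 genes lower and none higher (3 lower adjusted over the list alone, camera adjusted p = 0.314), among them cyclin-D3-1, LOC103927787 (-1.71 ± 0.21), and the histone H1.2-like gene LOC103961347 (-0.61 ± 0.09). Without untreated replicate 2 the cell division list passed camera downward (adjusted p = 0.004, median -0.16), and 1 of its genes fell without untreated replicate 1 or bagged replicate 3. The call of LOC103963535 was lost without untreated replicate 1 (adjusted p = 0.053) or bagged replicate 1 (0.0708). That of LOC103947710 was lost without untreated replicate 1 or 2 or bagged replicate 1 or 2 (0.0706 to 0.0974) and with the block (0.0548). That of LOC103961347 was lost without untreated replicate 1 or 3 or bagged replicate 1 or 3 (0.0503 to 0.0855) and with the block (0.0503).

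Markers of other tissue that a peel can hold were tested in 3 lists. Flesh sugar metabolism had 3 of 51 genes lower and none higher (9 lower and 7 higher adjusted over the list alone, camera adjusted p = 0.153) and a median of -0.24, with the polyol transporter genes LOC103964421 and LOC103936324 lower by 2.59 ± 0.39 and 1.47 ± 0.20. Without bagged replicate 2 no flesh sugar gene fell, and without untreated replicate 1 or bagged replicate 1 only 1 did. The flesh sugar median was -0.07 without untreated replicate 3 and -0.13 without untreated replicate 1 or bagged replicate 1. The call of LOC103964421 was lost without bagged replicate 1 (adjusted p = 0.0733) or 2 (0.0614), and that of LOC103936324 without untreated replicate 1 (0.0524) or bagged replicate 2 (0.0576). None of 12 phloem and xylem genes and none of 12 genes of the secondary wall of stone cells passed, over all genes or adjusted over the list alone (edgeR), and DESeq2 called 1 and 0 lower. Their camera adjusted p-values were 0.237 and 0.504, and the phloem and xylem list had a median of 0.24, a mean of -0.04 and an upward direction. Without untreated replicate 2 the phloem and xylem median was -0.01 and 1 gene fell, as with the block, and without untreated replicate 1 the median was 0.12. None of 276 cytosolic ribosomal protein genes passed (none adjusted over the list alone, 1 higher and 1 lower with DESeq2), with a median of 0.03 (-0.03 to 0.08 over all settings) and a camera adjusted p of 0.0831 (0.00878 without untreated replicate 1 and 0.00051 without bagged replicate 1).

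DESeq2 moved the counts of many lists by over 1.5 times. It called 7 cutin genes higher and 2 lower, 10 wax genes higher and 6 lower, 9 monolignol, 11 triterpene, 11 ethylene, 8 jasmonate, 7 cell wall and 10 MYB genes higher. It called 14 WRKY genes higher and 9 lower, 17 defence genes higher and 10 lower, and 7 heat shock genes higher and 4 lower. It also called 4 flesh sugar genes higher and 6 lower, 2 antioxidant genes higher and 4 lower, 8 auxin and 7 NAC genes lower, 3 light signalling and 3 clock genes lower, and 2 flavonoid and 2 laccase or peroxidase genes higher.

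In the authors' deposited table, adjusted p was below 0.05 for 1532 genes, 765 higher and 767 lower, and 1000 of them changed at least 2-fold. Across the 25139 tested genes the log2 fold changes in the authors' deposited table and those computed here had a Pearson correlation of 0.9999, where genes are not independent replicates. Of the 670 genes called here, 669 also pass in the authors' deposited table, all with the same sign. Both sets of calls rest on the same 6 libraries, so this overlap is no independent check. A further 792 tested genes pass in the authors' deposited table and not here.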

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

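Of the alternatives below, the robust fit and the list counts without each library were chosen after seeing the data. The count of 670 changed genes stayed within 1.5 times (578 to 834) under the other scalings, both other filters, limma-voom, limma on FPKM and the robust fit (660). DESeq2 called 1501 genes, 756 higher and 745 lower, and 931 at least 2-fold, and it holds 669 of the 670. Higher genes made up 36.4% of the calls, 27.6% with no scaling factors and 50.4% with DESeq2. An adjusted p below 0.01 left 106 genes, 19 higher and 87 lower, and a test against a 2-fold change left 86. Leaving out 1 library gave 205 to 692 changed genes, 70 to 306 higher and 135 to 386 lower, with 187 to 599 at least 2-fold and 8 to 13 lists past the camera threshold; fewer libraries leave a less precise test, and why the count rose without untreated replicate 3 was not tested. The labels name no pairing of samples, and deviations of same-numbered libraries from their group means correlated at -0.044, 0.083 and 0.057. Libraries of different numbers were not set beside them for scale, so these values do not settle whether replicate numbers pair samples. With the replicate number as a block 728 genes changed, 358 higher and 370 lower, 575 at least 2-fold, and 495 of them were among the 670. No list kept its camera call with an estimated correlation (0 lists against 10). The direction of camera, which can differ in sign from the median, turned in 7 lists that were not called; their medians there were those of the abscisic acid genes with no scaling factors (-0.0179), auxin without untreated replicate 2 (0.0325), cell wall genes with no filter (-0.0529), WRKY (0.0256), antioxidant (0.0178) and cell division genes (0.0207) without untreated replicate 1, and stone-cell genes under the CPM filter (0.1196); the cause was not tested. Of 392 list medians under these settings, 22 had the other sign than the reported ones, in 10 lists, at sizes up to 0.12; for WRKY this was so with upper quartile factors, no factors, limma-voom, the block, and without untreated replicate 2 or bagged replicate 1. Leave-one-out medians ran from -0.0645 to 0.0496 for auxin, -0.0114 to 0.0425 for WRKY, -0.0934 to 0.0178 for antioxidant and -0.1557 to 0.0207 for cell division genes. No named gene changed sign under the 14 alternatives run on named genes (not limma on FPKM, the robust fit or the stricter thresholds); of 48, the call was lost for 4 with the block, 3 with limma-voom, 1 with no factors and 5 to 23 with 1 library left out; 22 kept it without each library and 2 lost it without every one. The correlation with the authors' fold changes was 0.990 over all 32473 genes, which adds genes with few counts, and the first component held 59.0% of the variance of the 1000 most variable genes. Depth limits genes with few counts, and simulations recovered 44.9% of 2-fold changes.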

Other observations

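The tests of families, of the suberin scaling, flesh and common factor, of bagged-type skin in untreated replicate 3 and of the clock genes were chosen after the result was seen, and a limit of 0.5 (log2) on single departures was added to the common factor test once its outcome was known. Among 308 families scanned, 8 held more fallen and 4 more risen genes than other families (Fisher's exact test, 1-sided, Benjamini-Hochberg adjusted), a test that takes the genes of a family as independent. Camera passed 27 of the 308 with the preset correlation and none (0) with an estimated correlation, so no family is claimed to stand apart. With 1 library left out 5 to 11 families passed for fallen and 0 to 5 for risen genes, and with DESeq2 14 and 7. Only 4 of the 12 families passed without each library, all for fallen genes. GDSL esterases and lipases are a family with members that build or cut the cuticle polyesters. Of its 52 genes 9 were lower and 2 higher (Fisher adjusted p = 4.75e-05), none of them in a fixed list. DESeq2, though, called 13 higher and 9 lower, and camera put the family in the upward direction (adjusted p = 0.44 with the preset correlation). Without bagged replicate 2, 6 of them fell. The ABC transporter G family had 9 of 31 genes lower and 2 higher (adjusted p = 1.1e-06), of which 5 of the 9 stand in the suberin or cutin lists, with 6 lower without untreated replicate 1 or 2 and 5 without bagged replicate 1. The other 2 were non-specific lipid-transfer proteins (6 of 16 lower, 2 higher) and peroxidases (6 of 23 lower, 1 higher), whose changed genes all stand in fixed lists, and 3 lipid-transfer genes fell without bagged replicate 1. Cytochrome P450 genes, with 10 of 98 lower and 2 higher (adjusted p = 0.000935), did not pass without untreated replicate 2 (0.0828) or without bagged replicate 1, 2 or 3 (0.161, 0.943 and 0.112). Dirigent proteins (3 of 12 lower) and glycerol-3-phosphate acyltransferases (3 of 12 lower) also failed to pass without at least 1 library. So did genes described as a transcription factor with a code of letters and a number, MYB and TCP factors among them (12 of 151 lower, 2 higher). Of those 12 lower genes, 9 stand in fixed lists. No family passed for risen genes without each library. WRKY factors (7 of 63 higher, 5 lower, adjusted p = 0.00182) and 3-ketoacyl-CoA synthases (4 of 24 higher, 2 lower, adjusted p = 0.0199) are members of fixed lists. The WRKY family passed without untreated replicate 3 or bagged replicate 2 only, and the synthases and the pleiotropic drug resistance transporters (3 of 15 higher, 2 lower) passed in none of the 6 cases (0). The 21 kDa proteins had 3 of 11 higher (Fisher adjusted p = 0.0211), all on scaffold NW_008988257.1. These genes, outside the naming rule, were LOC103961967 (2.10 ± 0.20), LOC103961966 (1.34 ± 0.22) and LOC103961968 (0.75 ± 0.10). The family passed without untreated replicate 1 or 3 only, with 1 gene higher without untreated replicate 2 or bagged replicate 1.

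There are 10 ways to split the 6 libraries into 3 and 3, too few for a share below 0.05. The real split gave 670 changed genes against at most 1 in any other split, 527 against 1 for changes of at least 2-fold, and 10 lists past the camera threshold against 7. Only 1 of the 10 splits, the real one, reached each of these values. Every other split mixes bagged and untreated libraries, so the difference between bagged and untreated skin widens the spread within its groups. Few changed genes in those splits are therefore no measure of chance.

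The 13 suberin genes that fell did so by -3.25 to -2.26 (log2). Of the 5 that did not pass, LOC103945558 and LOC103951832, both outside the naming rule, stood at 0.11 and -0.24. LOC103948344, LOC103936171 and LOC103954218, also outside it, stood at -1.66, -2.11 and -1.98. Their average log2 CPM was low, at 1.29, 0.285 and -0.066. The choice among scalings is argued against, since the list median stayed at -2.789 or lower under 3 other scalings. These moved the median of all tested genes only from -0.0094 to between -0.0627 and -0.0058. A scaling error shared by these methods was therefore not tested. More flesh in the bagged peel would have lowered cutin genes as well if bagging left these genes unchanged, and their median was 0.5921. Its bootstrap 95% lower bound was 0.0226, which gives the spread over genes taken as independent, not over libraries. With 1 library left out the cutin median ran from 0.4488 to 0.7277. Cutin genes may themselves respond to bagging, so these values do not settle whether the bagged peel held more flesh. The flesh sugar list, not used in this test, had a median of -0.24, with 3 of 51 genes lower and 0 higher. As a hypothesis, bagged skin may hold a smaller share of one suberizing tissue, in which case the 13 fallen suberin genes would share one factor. None of the 13 (0) departed from their common mean at an adjusted p of 0.05 (limma). This cannot be told apart from low power, since a departure of 0.75 in LOC103931004, outside the naming rule, did not pass either (limma adjusted p = 0.111). The genes were also picked for having fallen, and a shared regulator would act alike.

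Untreated replicate 3 lay 38.5% of the way from the other untreated libraries to the bagged ones, against 14.2% and 7.69% for untreated replicates 1 and 2. On the same measure, bagged replicates lay 14.8% (replicate 1) to 25.7% (replicate 2) of the way toward the untreated libraries. Lower depth of untreated replicate 3 is argued against, since its place was 38.8% with all libraries thinned to the same total. If that library could hold skin of the bagged type, the share needed should be alike in both directions. It was 29.7% (25.8 to 33.5) from 270 genes that rose and 37.2% (34.2 to 38.9) from 236 that fell. Brackets hold bootstrap 95% intervals of the median over genes taken as independent. Each share was measured from the mean of the other untreated libraries, and so depends on them. Those shares lie apart by less than in untreated replicates 1 (0.45% and 10.005%) and 2 (0.883% and -47.7%) treated alike, a comparison added after the first outcome, so this explanation cannot be told apart from the ordinary spread of fruits. On the suberin list untreated replicates 1 to 3 stood at 1.12, 1.66 and 0.90 above the mean of the libraries (log2). Replicate 3 was thus nearer to replicate 1 than replicate 2 was. Biological variation in russet among untreated fruits was not tested.

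The 7 WRKY genes that rose include WRKY33 (LOC103962153), WRKY40 (LOC103938975), WRKY53 (LOC103943461) and WRKY18 (LOC103953687). They are known as early regulators of wound and pathogen responses, lie outside the naming rule and were chosen for mention after their values were seen. WRKY40, WRKY53 and WRKY18 lay near the floor, at 0 to 0.31 CPM in untreated and 0.86 to 6.11 CPM in bagged libraries. WRKY33 had 26.4 to 69.5 CPM in untreated and 160 to 344 CPM in bagged libraries. A wound or handling response at harvest may be involved. The median of 79 other wound and touch genes was 0.6643, with a bootstrap 95% interval of 0.40 to 0.89 over genes taken as independent. Camera gave p = 2.04e-07 but p = 0.162 with an estimated correlation, and 2 of these genes rose and 3 fell. The list was written without looking at its values, but 13 of its genes stand in fixed lists whose results had been seen. Without untreated replicate 3, whose values for the list (0.24) lay above those of untreated replicates 1 and 2 (-0.50 and -0.78) and of bagged replicate 2 (0.02, against 0.35 and 0.67 in bagged replicates 1 and 3), 16 rose and 3 fell and the median was 0.91. A different hour of harvest was weighed through the clock genes, whose median absolute change stood at percentile 89.49 of 10000 matched random lists, between the bounds set (the lower bound was moved from the 95th to the 50th percentile after that value was seen), so neither handling, hour nor the bag itself can be told apart here.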
